A study of Mus musculus with 10 samples.

How the data were processed

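Expression was measured in 10 samples of mouse splenic CD11c+ dendritic cells (DCs) on Affymetrix Mouse Gene 2.0 ST arrays, with 1 array per sample. The DCs came from wild-type (WT) mice or from mice lacking both C3ar1 and C5ar1 (DKO), 4 h after an injection of 100 µg CpG or vehicle, and were isolated with magnetic beads, per the labels. The deposited values are log2 intensities per probe set, which the authors made with RMA in Affymetrix Expression Console, per the labels. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of each probe set. The versions of both tools, the genome build, the probe set annotation and whether all arrays were normalized in 1 run are not given in the sources used here. Sorted values of the arrays differed by up to 0.240 on the log2 scale, so the distributions were nearly but not exactly equal. The amplification text names a kit used for a first batch of samples, while the extraction text names another protocol, and no sample is assigned to either. Batches therefore could not be assigned, and the numbers in the sample titles served as a stand-in, with titles numbered 20 and over forming the second title series.

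The table held 41345 probe sets and no missing values. Of these, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Only probe sets with 1 symbol were named, and 23328 of them also matched a gene of the reference table by gene identifier (assembly GRCm38.p6, used for names, chromosomes and the order of genes only). They covered 22180 genes. For the 1082 genes with more than 1 such probe set, the one with the highest mean over all 10 arrays was taken. A gene was tested where its value exceeded the array's median over all probe sets in at least 2 of the 10 arrays, which left 13371 genes. No detection calls were used, so a value near or below the array median may be near background.

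The 4 groups were WT unstimulated (n = 2), WT CpG (n = 3), DKO unstimulated (n = 2) and DKO CpG (n = 3). A linear model with 4 group means was fitted to all 10 arrays with limma 3.58.1 (lmFit and eBayes, neither trend nor robust) in R 4.3.3, with 6 residual and 4.49 prior degrees of freedom. It gave 7 contrasts: CpG in WT, CpG in DKO, DKO minus WT without stimulation, DKO minus WT after CpG, the difference of the CpG effects (DKO minus WT, the interaction), the CpG effect averaged over genotypes, and DKO minus WT averaged over stimulation. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested within a contrast, and a gene was called at an adjusted p under 0.05. Values after ± are standard errors of the contrast unless marked SD. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

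Gene lists were 26 in number: interferon-stimulated genes, inflammatory cytokines, chemokines, costimulation and maturation, NF-kB targets and feedback, MHC class I presentation, MHC class II presentation, glycolysis, oxidative phosphorylation, complement, the Toll-like receptor pathway, the unfolded protein response, the cell cycle, immediate-early and heat-shock genes, and markers of conventional DCs, cDC1, cDC2, plasmacytoid DCs, B cells, plasma cells, T cells, NK cells, neutrophils, monocytes, splenic macrophages and erythroid cells. The lists, the contrasts, the filter, the thresholds, the rule for naming genes and most alternatives were fixed before the data were examined. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, which compares the list with the other genes, and adjusted over the 26 lists within a contrast. Beside it stand camera with the correlation estimated from the data and fry. fry tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes or sets. Only the costimulation list (CpG in WT, CpG in DKO, CpG averaged over genotypes and DKO minus WT after CpG) and the NF-kB list (the 3 CpG contrasts) held with the estimated correlation.

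Genes were named by rule. The rule took C3ar1 and C5ar1, and for each contrast the 10 largest rises and 10 largest falls among called genes whose groups did not overlap. Predicted genes, clone names, small RNAs and variable segments of immunoglobulins and T cell receptors were only counted. Where fewer than 5 genes were called, the 5 with the smallest p were added and said not to pass. Up to 4 members with the smallest p were taken from each list with a call, and 12 genes were fixed by name (Tlr9, Il12b, Il6, Tnf, Cd40, Cd80, Cd86, Ccr7, C3, Cfb, C5ar2 and Hc). C3 was not among the genes with a probe set of 1 symbol and was not analysed here. Genes named outside this rule are said to be chosen after their values were seen.

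The pipeline was tested on simulated data of the same size, with 200 of 13371 genes changed. At a 2-fold change it recovered 95.5% of the changed genes for CpG in WT, 94.0% for CpG in DKO, 83.6% for DKO minus WT without stimulation, 92.5% for DKO minus WT after CpG and 37.3% for the interaction. The averaged contrasts each recovered 95.5% at that fold. At 1.5-fold the shares in the same order were 25.4%, 29.9%, 19.4%, 41.8% and 7.46%, with 86.6% for the averaged CpG effect and 77.6% for the averaged genotype effect. At 4-fold the lowest share was 97.0%, for the interaction. Between 5 and 10 unchanged genes were called per contrast, and no called gene had the wrong sign. Among 26 lists of independent simulated genes, of which 1 was shifted, camera called 1. The simulated noise was normal, independent between genes and set to each gene's variance as estimated by eBayes. Changing 200 genes at once also eases the adjustment. Genes of the real arrays vary together, as the neutrophil and macrophage markers show, so the recovered shares may be too high for them.

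Alternatives fixed beforehand were no filter, a filter at the 75th percentile, cyclic loess, quantile normalization or a median shift on top of the deposited values, the mean over the probe sets of a gene, eBayes with trend and robust, array weights, the title series as a block, a fold of at least 1.5, an adjusted p under 0.10, a fit on only the groups compared, leaving out each array in turn, camera with the estimated correlation, and fry. Chosen after seeing the data were leaving out the genes of the X and Y chromosomes, leaving out the 3 arrays with Y-linked signal, Y-linked signal as a covariate, leaving out the 3 arrays of the second title series, and the neutrophil or splenic macrophage marker level as a covariate. Probe sets with several symbols or none were left out of the gene tests because no gene could be named from them, and raw scanner files were not used here. The number of arrays limits the precision, and nothing in the labels says whether replicates came from separate mice, so the p-values measure only the spread between these samples.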

Results

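Gene expression was measured in splenic CD11c+ DCs, the antigen-presenting cells of the spleen, from WT mice and from mice lacking the complement anaphylatoxin receptors C3ar1 and C5ar1 (DKO). The mice had received 100 µg CpG, unmethylated DNA that Tlr9 recognises, or vehicle 4 h before isolation. There were 2 arrays of WT DCs without stimulation, 3 of WT DCs after CpG, 2 of DKO DCs without stimulation and 3 of DKO DCs after CpG. The highest array median was 5.56 on the log2 scale, the largest difference between sorted values of the arrays was 0.240, and the lowest single value was 1.63. Across the 13371 tested genes, arrays of the same group correlated at r = 0.964 to 0.989 (8 pairs) and arrays of different groups at 0.905 to 0.983 (37 pairs). These correlations are across genes, which are not independent replicates. The first principal component held 55.9% of the variance and the next held 15.0%.

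The targeted genes were read out at modest levels. C3ar1, the receptor for C3a, measured 5.95 and 5.80 in WT DCs without stimulation and 6.14, 6.31 and 6.59 after CpG. In DKO DCs it measured 5.64 and 5.27 without stimulation and 5.61, 5.55 and 5.34 after CpG. C5ar1, the receptor for C5a, measured 5.75 and 6.02 in WT DCs without stimulation and 6.64, 7.32 and 5.51 after CpG. In DKO DCs it measured 4.42 and 4.56 without stimulation and 4.99, 4.72 and 4.74 after CpG. All 5 DKO arrays were below all 5 WT arrays for each receptor. Averaged over stimulation, DKO minus WT was -0.63 ± 0.12 for C3ar1 (adjusted p = 0.0888) and -1.53 ± 0.27 for C5ar1 (adjusted p = 0.0786), so neither passed. Without WT CpG 3, C5ar1 passed at -1.78 (adjusted p = 0.00249), and with the neutrophil marker level as a covariate its difference was -0.68. C5ar1 also passed with the title series as a block, and both receptors passed with Y-linked signal as a covariate. The positions of the probes relative to the deleted parts are not given in the sources used here, so these values are no check of the genotype labels, and DKO values of C5ar1 lay below the array medians.

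The isolates differed in the markers of other cells and in sex-linked genes. S100a8, which with S100a9 encodes an abundant calcium-binding protein of neutrophils, measured 9.03 to 10.9 in the 5 WT arrays and 9.10, 8.27, 6.60, 4.82 and 4.40 in the DKO arrays. S100a9 measured 8.73 to 10.3 in WT and 8.71, 8.23, 6.67, 6.21 and 5.82 in DKO. Both genes were chosen after their values were seen, and neutrophil markers differed in how far they set the genotypes apart. Retnlg was at least 7.10 in WT and at most 6.64 in DKO, while Mmp9 measured 5.90 to 8.51 in WT and 6.14 to 8.04 in DKO. The median of the splenic macrophage markers, centred per gene, was 0.04 to 0.58 in the 5 WT arrays and 0.31 to 0.36 in 3 DKO arrays. In DKO unstimulated 2 and DKO CpG 3 it was -1.11 and -1.13. The 3 DKO arrays in the WT range (DKO unstimulated 1, DKO CpG 1 and DKO CpG 2) carried Y-linked signal, with a mean of Eif2s3y, Kdm5d and Uty of 7.67 ± 0.31 (SD), against 3.44 ± 0.14 (SD) in the other 7 arrays. Xist, the transcript of the inactive X chromosome, measured 4.62 ± 0.29 (SD) in these 3 and 10.6 ± 0.16 (SD) in the other 7. The labels do not state the sex of the mice. None of the 21 tested neutrophil markers and 3 of the 23 tested macrophage markers also stood in another list.

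What CpG changes in WT DCs was the first question. Interferon-stimulated genes, which carry the antiviral response, rose together. Of the 38 tested, 34 rose (35 adjusted over the list alone) and none fell, with a median log2 change of 1.95. Ifit1, an RNA-binding antiviral protein, rose by 3.47 ± 0.50, Ifi204, a DNA-sensing family member, by 2.60, Gbp5 by 2.79 and Rtp4 by 2.11. The list passed camera (adjusted p = 9.11e-25), but not against an estimated correlation (adjusted p = 0.322 with an estimated correlation). Costimulation and maturation genes, with which DCs engage T cells, followed the same direction, with 24 of 31 risen and 2 fallen (25 and 2 adjusted over the list alone) and a median of 1.28. Slamf1 rose by 3.48 ± 0.27 (adjusted p = 5.68e-05), Il2ra (CD25), the alpha chain of the interleukin-2 receptor, by 2.62 ± 0.21, Cd40 by 2.59 ± 0.22 and Pdcd1lg2, the inhibitory ligand PD-L2, by 2.44. Ccr7, which guides DCs to lymph nodes and T cell zones, rose by 1.41, Cd80 by 0.92 and Cd86 by 0.57. This list passed camera (adjusted p = 4.68e-19) and also held with the estimated correlation (adjusted p = 0.00711).

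NF-kB targets and feedback genes rose in 23 of 30 cases and none fell (25 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 1.33e-17, and 0.00711 with the estimated correlation). Tnip3, an inhibitor of NF-kB signalling, rose by 3.89 ± 0.36 (adjusted p = 0.000103). Bcl3 rose by 1.82, Cflar, which blocks death-receptor signalling, by 1.53 and Birc2 by 1.48. Of 25 inflammatory cytokines, 12 rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 0.82. Il6 rose by 3.09 ± 0.27, Il27 by 2.85 ± 0.22, Il12b, the shared subunit of IL-12 and IL-23, by 2.60 ± 0.32 and Tnf by 1.94 ± 0.27. Il1rn, an antagonist of interleukin-1, rose by 2.19 and Ebi3, the partner chain of Il27, by 1.73. The cytokine list passed camera (adjusted p = 3.40e-07) but not with an estimated correlation (adjusted p = 0.322 with an estimated correlation). Of 22 chemokines, 12 rose and 1 fell (13 and 1 adjusted over the list alone), among them Ccl17 by 2.53, Cxcl10 by 2.46 and Ccl22 by 1.83. Their median of 0.93 passed camera (adjusted p = 7.98e-08) but not with an estimated correlation (adjusted p = 0.322 with an estimated correlation). MHC class I genes rose in 7 of 21 cases (7 adjusted over the list alone), including the transactivator Nlrc5 by 1.10 and the peptide transporter Tap1 by 0.66, with a median of 0.17 (camera adjusted p = 0.0127, and adjusted p = 0.543 with an estimated correlation). Outside the lists, Car13 rose by 3.30, Lipg by 3.19, Muc1 by 3.08, Csta3 by 3.03 and Tarm1, a receptor of the leukocyte immunoglobulin-like family, by 2.86 ± 0.18. Tlr9 itself changed by 0.43 and did not pass (adjusted p = 0.138).

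Markers of cDC1, the cross-presenting DC subset, fell in WT DCs after CpG. Of 20 tested cDC1 markers, 4 of which another list also holds, 13 fell and 4 rose (15 and 4 adjusted over the list alone), with a median of -1.04. The falls included Xcr1, the chemokine receptor of cDC1, at -2.54 ± 0.18 (adjusted p = 4.45e-05), Tlr3 at -2.54 ± 0.25, Tlr11 at -2.20 and Naaa at -2.02. Ly75, the endocytic receptor DEC-205 in the same list, rose by 2.28. The list passed camera (adjusted p = 0.000185), and adjusted p = 0.368 with an estimated correlation. Conventional DC core markers fell in 7 of 13 cases and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.0402, and adjusted p = 0.705 with an estimated correlation). Another list held 3 of these markers. Among the falls were Snx22 at -1.54, Ciita, the MHC class II transactivator, at -0.79 and Itgax, which encodes CD11c, at -0.76. Cell cycle genes fell in 11 of 38 cases and none rose (14 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 4.08e-05, and adjusted p = 0.705 with an estimated correlation). They included E2f1 at -1.13, the replication helicase subunit Mcm2 at -1.12 and Cdc6 at -1.08. Immediate-early and heat-shock genes fell in 9 of 31 cases and rose in 2 (12 and 3 adjusted over the list alone), with Dusp6, an ERK phosphatase, at -2.26, Nr4a2 at -0.94 and Fosb at -0.81. Their median of -0.25 gave a camera adjusted p = 0.0402, and adjusted p = 0.825 with an estimated correlation. Outside the lists, Hepacam2 changed by -2.99 ± 0.38, Abcd2 by -2.75, Lrrk2 by -2.71, Rab7b by -2.63 and Kcnj16 by -2.54.

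Neutrophil markers rose in 3 of 21 cases and none fell (3 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 0.00688, and adjusted p = 0.825 with an estimated correlation). Wfdc21 was 1 of them, at 2.14. The median fell short without WT CpG 2, at 0.32 (adjusted p = 0.0840), and was 1.36 without WT CpG 3. In the Toll-like receptor pathway 9 of 35 rose and 6 fell (11 and 8 adjusted over the list alone), with Cd180, a surface relative of the Toll-like receptors, at -1.55 and Tlr12 at -1.17 (median 0.13, camera adjusted p = 0.521). Complement genes rose in 2 of 24 cases and fell in 5 (3 and 5 adjusted over the list alone), with a median of -0.12, a mean of 0.0059 and a camera adjusted p = 0.911. Cfb, a factor of the alternative pathway, rose by 2.01 ± 0.31, Hc, which encodes C5, rose by 0.79, and C5ar2 fell by 0.59. B cell markers fell in 8 of 22 cases and rose in 1 (8 and 2 adjusted over the list alone), including Bank1 at -1.56 and Cd22 at -1.44 (median -0.19, camera adjusted p = 0.241). Of 22 glycolysis genes 4 rose and 3 fell, the same counts as adjusted over the list alone. Pfkfb3, which drives glycolytic flux, rose by 1.34 and the glucose transporter Slc2a3 fell by 1.30, and the list's median of -0.04 differed in sign from its mean of 0.03 and from its test (adjusted p = 0.569).

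Camera did not call the other 11 lists in WT DCs, which are given with members risen, members fallen and median log2 change. MHC class II genes had 0, 3 and -0.10 (adjusted p = 0.538), oxidative phosphorylation had 0, 1 and -0.09 (adjusted p = 0.613) and the unfolded protein response had 3, 2 and -0.02 (adjusted p = 0.569, tested upward). The cDC2 markers had 1, 3 and -0.17 (adjusted p = 0.538) and plasmacytoid DC markers had 1, 3 and -0.16 (adjusted p = 0.640). Plasma cell markers had 1, 0 and -0.02 (mean 0.21, adjusted p = 0.300), T cell markers had 1, 1 and -0.04 (adjusted p = 0.925, tested upward) and NK cell markers had 3, 1 and 0.42 (adjusted p = 0.111). Monocyte markers had 2, 3 and 0.17 (adjusted p = 0.640), splenic macrophage markers had 1, 1 and -0.26 (adjusted p = 0.538) and erythroid markers had 0, 1 and -0.16 (adjusted p = 0.521). Adjusted over the list alone, these counts differed for MHC class II (0 and 2), oxidative phosphorylation (0 and 0) and the unfolded protein response (3 and 3).

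In WT DCs, limma called 2885 of 13371 genes after CpG, 1102 higher and 1783 lower, and 4368 had an unadjusted p under 0.05. The count was 1416 without WT unstimulated 1 and 1277 without WT unstimulated 2. Cd86 and Itgax did not pass without WT unstimulated 2 (adjusted p = 0.0717 and 0.0599), nor did Ciita and Wfdc21 (0.133 and 0.0644), Hc did not pass without either unstimulated array (0.0572 and 0.0695), and C5ar2 did not pass without either of them or WT CpG 1 (0.0589, 0.118 and 0.0510). Single arrays also ended the camera calls of MHC class I genes (adjusted p = 0.0615 without WT unstimulated 1), of immediate-early genes (0.365 without WT unstimulated 2, 0.157 without WT CpG 3 and 0.0588 without DKO CpG 1), of conventional DC markers (0.112 without WT unstimulated 2, 0.0514 without WT CpG 1 and 0.0840 without WT CpG 2) and of neutrophil markers (0.108 without WT unstimulated 1).

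Interferon-stimulated, NF-kB, costimulation, cytokine and chemokine genes rose with CpG in DKO DCs as well. NF-kB targets rose in 18 of 30 cases and none fell (24 adjusted over the list alone), with a median of 0.79, and costimulation genes rose in 20 of 31 cases and fell in 1 (24 and 2 adjusted over the list alone), with a median of 0.85. Tnip3 rose by 3.89 ± 0.36, Il6 by 3.06 ± 0.27 (adjusted p = 0.000296), Il12b by 2.87 ± 0.32, Slamf1 by 2.83 ± 0.27, Cd40 by 2.24 ± 0.22 and Tnf by 2.14 ± 0.27. Ccr7 rose by 1.14, Cd80 by 0.75 and Cd274, the inhibitory ligand PD-L1, by 1.23. Both lists passed camera (adjusted p = 7.03e-21 and 2.03e-17) and held with the estimated correlation (adjusted p = 0.00859 and 0.00925). Interferon-stimulated genes rose in 28 of 38 cases and none fell (34 adjusted over the list alone), with a median of 1.41, among them Oasl1 by 2.71 and Ifi204 by 2.69. Chemokines rose in 10 of 22 cases and none fell (12 adjusted over the list alone), with Ccl17 at 1.63 and a median of 0.75, and cytokines rose in 6 of 25 cases and fell in 2 (10 and 2 adjusted over the list alone), with a median of 0.66. These 3 lists passed camera (adjusted p = 3.00e-24, 5.73e-09 and 3.56e-07), but each had an adjusted p = 0.307 with an estimated correlation.

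The lists that fell in DKO DCs overlapped in part with those in WT. The cDC1 markers fell in 6 of 20 cases and rose in 2 (8 and 2 adjusted over the list alone), with a median of -0.43, and Tlr3 changed by -2.17, Xcr1 by -1.71 and Tlr11 by -1.54. The list passed camera (adjusted p = 0.0254, and adjusted p = 0.561 with an estimated correlation), though not without DKO unstimulated 1 (0.214) or DKO CpG 3 (0.0670). Cell cycle genes fell in 6 of 38 cases (12 adjusted over the list alone), including the cytokinesis protein Prc1 at -0.81, with a median of -0.42 (camera adjusted p = 3.36e-07, and adjusted p = 0.552 with an estimated correlation). Conventional DC markers fell in 3 of 13 cases (5 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.0193, and adjusted p = 0.552 with an estimated correlation). B cell markers fell in 5 of 22 cases (6 fallen and 2 risen adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.0226, and adjusted p = 0.552 with an estimated correlation). Both calls ended without DKO CpG 1 (0.0530 and 0.0784) or DKO unstimulated 2 (0.160 for each). Neutrophil markers had a median of 0.87 with 1 gene risen (camera adjusted p = 0.0193, and adjusted p = 0.7499 with an estimated correlation), which ended without DKO CpG 1 (0.121), DKO CpG 2 (0.0683) or DKO unstimulated 2 (0.0886). Immediate-early genes, which passed in WT, had 8 of 31 fallen and 2 risen (the same adjusted over the list alone) and a median of -0.16, and did not pass camera (adjusted p = 0.0711). MHC class I genes, which also passed in WT, had 0 of 21 risen or fallen by limma and a median of 0.02 (camera adjusted p = 0.332). In the test of the difference between the CpG effects, MHC class I genes passed camera (adjusted p = 0.0143, and adjusted p = 0.879 with an estimated correlation), and immediate-early genes (0.405) and B cell markers (0.562) did not. Hepacam2 changed by -2.41 ± 0.38, Lrrk2 by -1.99, Kcnj16 by -1.74, Tifab by -1.63 and Dusp6 by -1.55.

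In DKO DCs, limma called 1377 genes after CpG, 607 higher and 770 lower, and 3344 had an unadjusted p under 0.05. Without DKO unstimulated 1 the count was 773, without DKO unstimulated 2 it was 423 and without DKO CpG 1 it was 735. Of these 1377 genes, 1137 were also called in WT, and 1136 changed in the same direction, 530 up and 606 down. Another 1748 genes were called in WT only, and 96.5% of them had the same sign in DKO. Across genes, which are not independent replicates, the changes correlated at r = 0.827 with a slope of 0.653 for DKO on WT, and r was 0.713 without DKO unstimulated 1. A gene called in 1 genotype only is not shown to differ between them, for which the difference of the effects was tested.

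**Figure D1:**
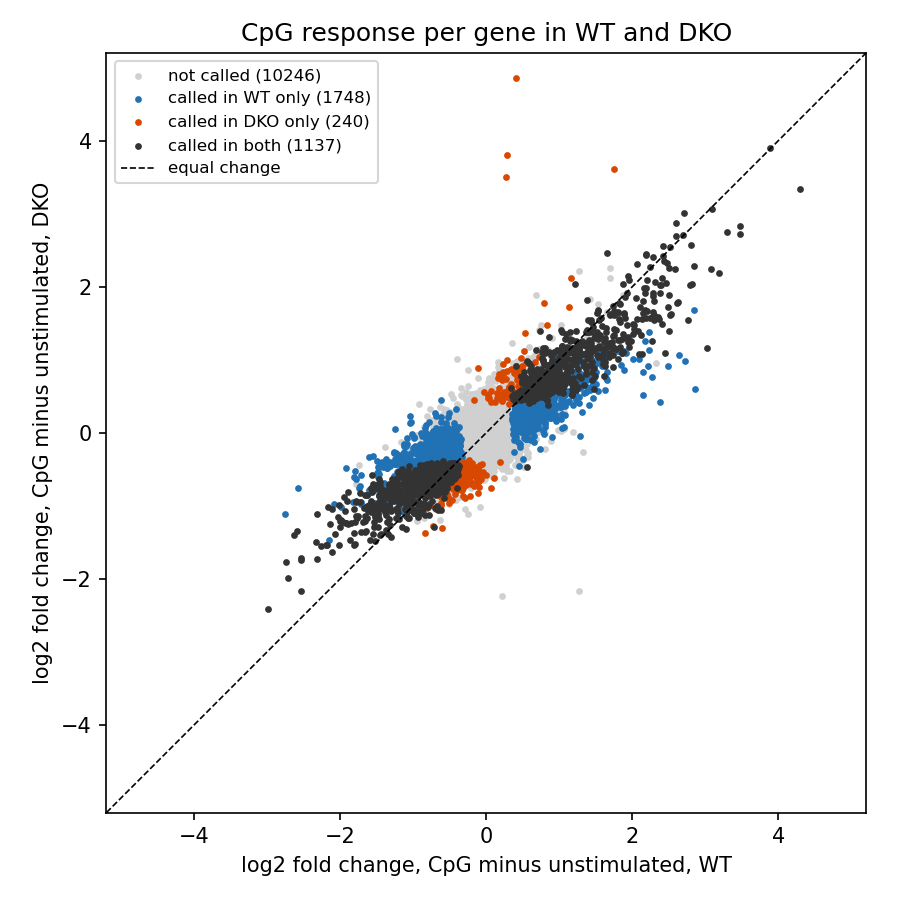
Each point is 1 of the 13371 tested genes, with its log2 change after CpG in WT DCs on the horizontal axis and in DKO DCs on the vertical axis; colours mark genes called in both genotypes (1137), in WT only (1748), in DKO only (240) or in neither, and the dashed line marks equal change. Most called genes lie in the quadrants of equal sign (r = 0.827 across genes), with a slope of 0.653.

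Averaged over genotypes, the CpG effect rested on 6 arrays against 4. Il6 rose by 3.07 ± 0.19 (adjusted p = 5.84e-06), Cd40 by 2.42 ± 0.15, Il12b by 2.74 ± 0.22 and Mab21l3, the gene with the smallest p, by 2.85 ± 0.11 (adjusted p = 1.03e-06). Xcr1 changed by -2.13 ± 0.13, Tlr3 by -2.36 ± 0.18 and Serpinb8 by -1.92 ± 0.19. Cell cycle genes fell in 20 of 38 cases (29 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 6.82e-07, and adjusted p = 0.622 with an estimated correlation). limma called 3978 genes, 1493 higher and 2485 lower.

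Without stimulation, the question was whether DKO DCs differ from WT DCs at rest. Gm15448, a predicted gene chosen after its values were seen, was the single called gene, at -4.69 ± 0.19 (adjusted p = 1.56e-06), with means of 8.86 ± 0.06 (SD, n = 2) in WT and 4.16 ± 0.19 (SD, n = 2) in DKO. The DKO level lay below the array medians and may be near background, in which case the difference is a lower bound. Predicted genes and small RNAs aside, the genes with the next smallest p did not pass, with C5ar2, the other C5a receptor, at -0.96 (adjusted p = 0.280), Dnah8 at 0.83 (adjusted p = 0.232), Slc1a5 at -0.81 (adjusted p = 0.280), Cd59a at -0.85 and Irgc1 at 0.68 (adjusted p = 0.391 for both). Il12b, Il6, Tnf and Cd40 did not pass, at -0.45, -0.70, -0.44 and -0.11. Neutrophil markers, 18 of 21 of them below 0, had a median of -0.91 and none called (6 lower adjusted over the list alone), and splenic macrophage markers had a median of -0.89. Both passed camera (adjusted p = 1.62e-08 and 5.93e-08), and both had an adjusted p = 0.429 with an estimated correlation. Complement genes had a median of -0.34 with none called and 2 lower adjusted over the list alone (camera adjusted p = 3.24e-08, and adjusted p = 0.429 with an estimated correlation). This list holds the targeted C3ar1 and C5ar1 and also C5ar2. Part of its shift in each genotype contrast may therefore follow from the targeting itself. Of its 24 tested members, 7 also stood in another list. limma called 1 gene, and 619 had an unadjusted p under 0.05.

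Camera called 13 lists between the resting genotypes, and none held with the estimated correlation or by fry. Neutrophil markers, complement genes, chemokines (-0.28), NF-kB targets (-0.16) and cell cycle genes (0.19) kept their calls in every fit that left out 1 array. Each had an adjusted p = 0.429 with an estimated correlation. With the neutrophil marker level as a covariate, the medians of NF-kB targets (0.025), cell cycle genes (-0.0029), cytokines (0.037) and conventional DC markers (-0.033) turned sign. None of them passed camera there (adjusted p from 0.671 to 0.985). The calls of 8 lists ended in at least 1 fit that left out 1 array. Without WT unstimulated 1 these were interferon-stimulated genes (median -0.18 with all arrays, adjusted p = 0.0822 without it), costimulation genes (-0.11, 0.108) and conventional DC markers (0.17, 0.287), and without WT unstimulated 2 glycolysis (-0.11, 0.188) and the Toll-like receptor pathway (-0.11, 0.254). Without DKO unstimulated 2 they were cytokines (-0.15, 0.125), cDC1 markers (-0.21, 0.210), glycolysis (0.297), conventional DC markers (0.313) and splenic macrophage markers, whose median was then -0.19 (0.103). Without DKO unstimulated 1 they were interferon-stimulated genes (0.119), costimulation genes (0.761) and the Toll-like receptor pathway (0.230), and the macrophage median was then -1.57. Without DKO CpG 3 the costimulation list had an adjusted p = 0.0503. The gene count was 2 without DKO CpG 2 and without WT CpG 3. It was larger with Y-linked signal as a covariate and in a fit on only the groups compared, as given under the processing below.

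After CpG, 16 genes differed between DKO and WT DCs, 9 lower and 7 higher in DKO. Gm15448, chosen after its values were seen, was lower at -3.51 ± 0.15 (adjusted p = 3.81e-06). Tarm1 followed at -2.27 ± 0.16 (adjusted p = 0.000264), with means of 10.3 ± 0.07 (SD, n = 3) in WT and 8.05 ± 0.37 (SD, n = 3) in DKO. Il23r, a receptor chain for interleukin-23, was lower at -1.25 ± 0.14 (adjusted p = 0.00784), Il2ra by -1.26 ± 0.19 (adjusted p = 0.0440) and Pirb, an inhibitory receptor for MHC class I, by -1.18 ± 0.17 (adjusted p = 0.0341). Stfa2l1, a member of the neutrophil marker list, was lower at -1.95, the cystatin-like gene Csta3 at -1.90, Gp2 at -1.24 and Kcne3 at -0.80. Abca3, a lipid transporter, was higher by 1.25 ± 0.13 (adjusted p = 0.00784), and Ifngr1, a chain of the interferon-gamma receptor, was higher by 0.97 ± 0.13 (adjusted p = 0.0225). Glo1, Atp10d, Mapk14, which encodes the kinase p38 alpha, Tmem160 and Hectd4 were higher by 0.96, 0.96, 0.94, 0.74 and 0.72. Of these 16 genes, 14 also changed with CpG averaged over genotypes. All 16 had the same sign without stimulation, but only Gm15448 was called there. For some the difference without stimulation was near 0, as for Tarm1 (means of 7.47 in WT and 7.45 in DKO) and Kcne3 (5.36 and 5.33). Without stimulation Csta3 (3.36 and 3.32) and Il23r (4.24 and 4.01) lay below the array medians and may be near background.

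**Figure D2:**
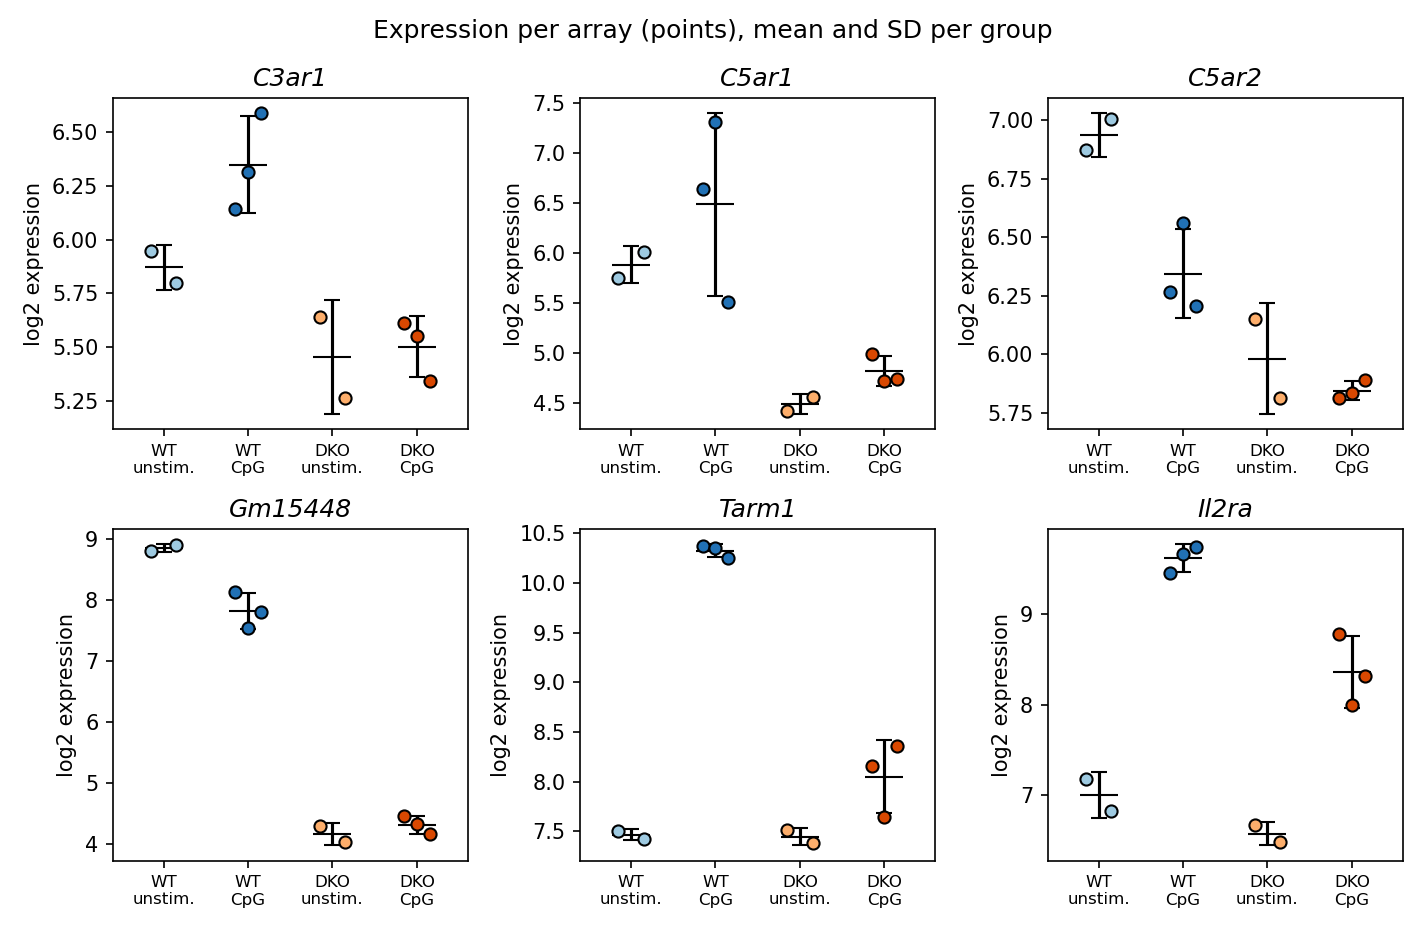
Log2 expression of C3ar1, C5ar1, C5ar2, Gm15448, Tarm1 and Il2ra in the 4 groups, with 1 point per array and the mean and SD of each group. Tarm1 rose from 7.47 to 10.3 in WT DCs and measured 7.45 and 8.05 in DKO DCs, while Gm15448 was low in all 5 DKO arrays.

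The cytokines and costimulatory molecules most used to describe DC maturation did not pass between genotypes after CpG. Il12b differed by -0.19 (adjusted p = 0.828), Tnf by -0.23 (0.722), Il6 by -0.73 (0.201), Cd40 by -0.46 (0.315), Cd80 by -0.14 (0.644), Cd86 by -0.19 (0.429) and Ccr7 by -0.43 (0.159). Cfb differed by -0.67, Hc by -0.37 and C5ar2 by -0.50 without passing. As a group, costimulation genes were lower in DKO, with 28 of 31 below 0 and a median of -0.36, 1 of them called over all genes and 15 lower and 1 higher adjusted over the list alone. Besides Il2ra these included Slamf1 at -1.25, Tnfrsf9 at -0.86 and Pdcd1lg2 at -0.67, which did not pass over all genes. The list passed camera (adjusted p = 5.94e-13), also with the estimated correlation (adjusted p = 0.0400), and passed fry (adjusted p = 0.00476). The 6 arrays after CpG allow 10 splits, too few for a permutation p under 0.05. Interferon-stimulated genes had a median of -0.67, with 37 of 38 below 0 and none called (21 lower adjusted over the list alone), and passed camera (adjusted p = 4.55e-17) but not with an estimated correlation (adjusted p = 0.370 with an estimated correlation). The list's centred medians per array after CpG were 0.91, 0.77 and 1.36 in WT. In DKO they were 0.73, -0.32 and 0.54, with DKO CpG 2 the lowest. Chemokines (-0.38), cytokines (-0.33) and MHC class I genes (-0.16) also passed camera (adjusted p = 6.92e-07, 6.51e-06 and 0.000693, and adjusted p = 0.370 with an estimated correlation for each), as did NF-kB targets at -0.19 (1.57e-05, and adjusted p = 0.164 with an estimated correlation). The cytokine median turned to 0.064 with the neutrophil marker level as a covariate and did not pass camera there (adjusted p = 0.728).

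Markers of other cells moved with these groups after CpG. Neutrophil markers had a median of -1.45 in DKO minus WT, with 20 of 21 below 0 and Stfa2l1 the 1 called (11 lower adjusted over the list alone), and Retnlg and Mmp8 measured -3.12 and -2.63 without passing. The list passed camera (adjusted p = 1.78e-11, and adjusted p = 0.370 with an estimated correlation). Cell cycle genes had a median of 0.20 (camera adjusted p = 2.43e-05) and conventional DC markers 0.21 (camera adjusted p = 0.0136), both with an adjusted p = 0.603 with an estimated correlation. Complement genes, among them the targeted C3ar1 and C5ar1, had a median of -0.28 (camera adjusted p = 0.0107, and adjusted p = 0.603 with an estimated correlation). Plasmacytoid DC markers had a median of 0.31 (camera adjusted p = 0.0167, and adjusted p = 0.624 with an estimated correlation). Without DKO CpG 3 the calls of complement genes (-0.04, adjusted p = 0.232), cell cycle genes (0.0627) and conventional DC markers (0.209) ended, the last also without WT CpG 2 (0.0755). The plasmacytoid call ended without DKO CpG 1 (0.223) or WT CpG 3 (0.213). Complement genes turned to 0.14 and conventional DC markers to -0.086 with the neutrophil marker level as a covariate, and plasmacytoid DC markers to -0.053 with Y-linked signal as a covariate. None of them passed camera in those fits (adjusted p = 0.876, 0.909 and 0.634, in that order).

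**Figure D3:**
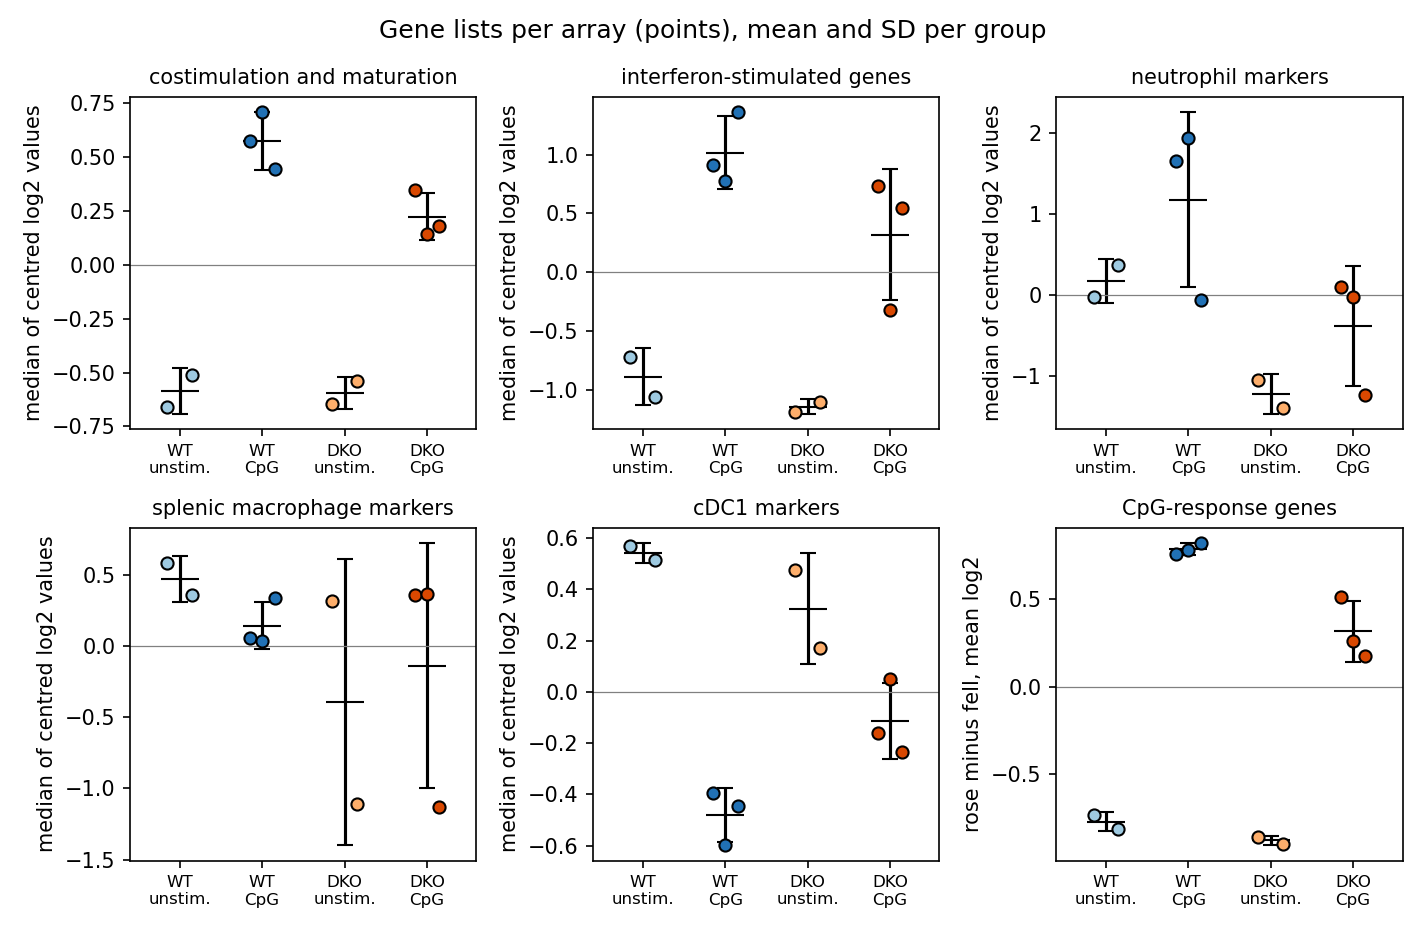
Median centred log2 value per array of the costimulation, interferon-stimulated, neutrophil, splenic macrophage and cDC1 lists, and the mean of the genes that rose minus those that fell with CpG, in the 4 groups with 1 point per array and the mean and SD. The costimulation score was 0.57 in WT and 0.22 in DKO after CpG, and the macrophage markers measured -1.11 and -1.13 in 2 DKO arrays.

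limma called 16 genes between genotypes after CpG, and 1918 had an unadjusted p under 0.05. In fits that left out 1 array only Gm15448 and Tarm1 of the 16 kept their calls throughout, and the count was 2 without WT CpG 1, WT CpG 2 or DKO CpG 2, 7 without either DKO unstimulated array, 8 without DKO CpG 3, 29 without WT CpG 3 and 267 without DKO CpG 1. With the 3 arrays carrying Y-linked signal left out 723 genes were called, from 1 DKO CpG array (DKO CpG 3, low in macrophage markers at -1.13) against 3 WT arrays. With Y-linked signal as a covariate, whose effect only the DKO arrays can estimate, 738 were called, with the title series as a block 296 and with the neutrophil marker level as a covariate 9.

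Averaged over stimulation, 13 genes differed between genotypes, 8 lower and 5 higher in DKO. Gm15448 was lower at -4.10 ± 0.12 (adjusted p = 6.72e-08), Tarm1 by -1.14 ± 0.13 (adjusted p = 0.0210), Pirb by -0.97 ± 0.13, Gp2 by -0.92 ± 0.13, Il23r by -0.75 ± 0.11 and C5ar2 by -0.73 ± 0.10 (adjusted p = 0.0315). The predicted genes Gm1965 and Gm10693, chosen after their values were seen, were lower at -0.83 and -0.78. Glo1, which detoxifies methylglyoxal, was higher by 0.86, Abca3 by 0.84, Dnah8 by 0.65, Tmem160 by 0.62 and Btbd9 by 0.56. Of these 13 genes, 7 lay on the chromosome of C5ar1 (53.8%), which held 8.11% of the tested genes (two-sided Fisher's exact test, p = 2.52e-05). In the order of tested genes, C5ar2 was 1 gene from C5ar1, Tmem160 was 6, Gm10693, Gm15448 and Pirb were 79 to 81, Tarm1 was 90 and Gp2 was 702 away. On another chromosome, Glo1 and Btbd9 were each 1 tested gene from the nearest other called gene and Dnah8 was 2 away. Fisher's test takes the called genes as independent, which genes lying side by side are not, so its p-values here are likely too small. After CpG, 6 of 16 called genes were on the chromosome of C5ar1 (two-sided Fisher's exact test, p = 0.00111). The chromosome of C3ar1, the other targeted gene, held 2 of the 13 (two-sided Fisher's exact test, p = 0.140) and 1 of the 16 (two-sided Fisher's exact test, p = 0.567). Of the genes called for CpG averaged over genotypes, 7.53% were on the chromosome of C5ar1 (two-sided Fisher's exact test, p = 0.111).

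Of the lists averaged over stimulation, neutrophil markers (median -1.33, camera adjusted p = 3.73e-14), interferon-stimulated genes (-0.41, 1.13e-14) and costimulation genes (-0.29, 7.03e-10) had the smallest camera p. None of the 12 lists camera called held with an estimated correlation, where these 3 had adjusted p = 0.296, 0.377 and 0.0845. With the neutrophil marker level as a covariate, 6 of the 12 turned sign, namely cytokines (0.063), chemokines (0.0046), NF-kB targets (0.016), complement genes (0.035), conventional DC markers (-0.070) and macrophage markers (0.16). None of these 6 passed camera there (adjusted p from 0.156 to 0.991). Plasmacytoid DC markers turned to -0.10 with the arrays carrying Y-linked signal left out or that signal as a covariate and to -0.025 without DKO unstimulated 1, and macrophage markers to 0.049 without the second title series. limma called 13 genes, and 1556 had an unadjusted p under 0.05. More genes were called with the title series as a block, as given under the processing below. The count was 1 without WT unstimulated 2, WT CpG 1, WT CpG 2 or either DKO unstimulated array, 2 without WT unstimulated 1, 4 without DKO CpG 2, 35 without WT CpG 3 and 71 without DKO CpG 1, and Gm15448 kept its call throughout. With the arrays carrying Y-linked signal left out, which leaves 1 DKO array without stimulation and 1 after CpG, the count was 987, and with the neutrophil marker level as a covariate it was 3.

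Whether the response to CpG itself differs between genotypes was tested as the difference of the 2 effects. Tarm1 was the single called gene, at -2.25 ± 0.26 (adjusted p = 0.0490), having risen by 2.86 in WT DCs. With the title series as a block it was -2.21 and did not pass (adjusted p = 0.0669), and over the alternatives other than leaving out 1 array it ran from -2.50 to -1.88, with adjusted p from 0.0143 to 0.0914. The next smallest p belonged to Pdcd1lg2 at -1.35 and Prrt2 at -1.03 (adjusted p = 0.509 for both), Arhgap32 at 1.24 and Cd59a at 1.07 (adjusted p = 0.635 for both), which did not pass. The responses of Il6, Il12b, Tnf and Cd40 differed by -0.03, 0.26, 0.20 and -0.35, those of Cd80, Cd86 and Ccr7 by -0.16, -0.08 and -0.26, and none passed. Camera called 5 lists, none of them with an estimated correlation. Interferon-stimulated genes had a median difference of -0.43 (adjusted p = 1.30e-05, and adjusted p = 0.879 with an estimated correlation), costimulation genes -0.26 (4.60e-06, and adjusted p = 0.235 with an estimated correlation) and MHC class I genes -0.19 (0.0143, and adjusted p = 0.879 with an estimated correlation). The cDC1 markers had 0.57 (1.30e-05, and adjusted p = 0.652 with an estimated correlation) and splenic macrophage markers 0.42 (0.0487, and adjusted p = 0.879 with an estimated correlation), while neutrophil markers had -0.15 (0.331).

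The CpG response as a whole was smaller in DKO DCs by these medians. Of the 1493 genes that rose with CpG averaged over genotypes, 71.9% rose less in DKO, with medians of 0.70 in WT and 0.53 in DKO and a median difference of -0.15. Of the 2485 that fell, 73.6% fell less in DKO, with medians of -0.59 and -0.45 and a median difference of 0.16. The averaged CpG effect and its difference between genotypes are independent in this design, so choosing the genes by the first does not bias the second. Over the 60 splits of the arrays within stimulation, the exact permutation p was 0.167 for the genes that rose and 0.133 for those that fell. Splits that exchange only the unstimulated labels carry any genotype difference into the difference of effects. The splits therefore cannot decide alone. For the risen and fallen genes, camera with the estimated correlation gave p = 0.0111 and 0.0327, and fry gave p = 0.0357 and 0.0463. The mean of risen minus fallen genes was 0.75, 0.78 and 0.82 in WT arrays after CpG and 0.51, 0.26 and 0.17 in DKO arrays. With the genes chosen again in each fit that left out 1 array, the median difference of the risen genes was -0.07 without DKO unstimulated 1, -0.08 without DKO CpG 3 and -0.23 without WT unstimulated 1, and that of the fallen genes was 0.09 without DKO CpG 3. In such fits the groups are of unequal size and the independence no longer holds.

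For the difference of the effects limma called 1 gene, and 756 had an unadjusted p under 0.05. Tarm1 kept a difference between -2.40 and -2.05 in every fit that left out 1 array but passed only without DKO CpG 2 or DKO CpG 3, with adjusted p of 0.465 and 0.621 without the WT unstimulated arrays, 0.296, 0.256 and 0.0847 without the WT CpG arrays, 0.205 and 0.322 without the DKO unstimulated arrays and 0.135 without DKO CpG 1. The interferon-stimulated call ended without DKO CpG 2 (-0.20, adjusted p = 0.147), the MHC class I call without WT unstimulated 1, DKO unstimulated 1, DKO CpG 2 or WT CpG 3 (0.111, 0.139, 0.116 and 0.0888), and the macrophage call in 6 such fits, with a median of -0.27 without DKO unstimulated 2 (adjusted p = 0.696) and 1.14 without DKO unstimulated 1. With the title series as a block the macrophage median was -0.018.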

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

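The tests of the chromosome of C5ar1, of the sex-linked signal for the genes differing between genotypes, and of the title series and the sex-linked signal for the neutrophil and macrophage markers were chosen only after the result was seen.

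A test of the difference between the CpG effects in the 2 genotypes picked out Tarm1 at -2.25 and 5 lists: interferon-stimulated genes at -0.43, costimulation genes at -0.26, MHC class I genes at -0.19, cDC1 markers at 0.57 and splenic macrophage markers at 0.42. It also picked out the genes that rose with CpG, at -0.15, and those that fell, at 0.16. For the genes called by this test, 4 of 60 splits of the arrays within stimulation gave as many as the real split (1 gene, highest other split 13), so chance was not excluded. The split with 13 genes exchanges only the unstimulated labels, so its difference of effects is the sum of the genotype differences without and with CpG. Splits of this kind hold a genotype difference where there is one. The splits therefore cannot decide on chance for the difference of effects, neither for this count nor for the lists. For the lists, the exact p over these splits was 0.433 for interferon-stimulated genes, 0.15 for costimulation genes, 0.117 for MHC class I genes, 0.533 for macrophage markers and 0.0167, the smallest the splits can give, for cDC1 markers (0.433 adjusted over the 26 lists), so chance was not excluded for any of the 5 after adjustment. Outside the genes with 1 symbol, 259 of 8833 tested probe sets with several symbols (58) or none (201) passed for CpG averaged over genotypes, a signal in data the comparisons do not use.

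The first pattern weighed was that genes differing between genotypes often lay on the chromosome of C5ar1. Only C5ar2 and Tmem160 were close to C5ar1, at 1 and 6 tested genes. The other called genes on its chromosome were 79 to 702 tested genes away. The share of called genes on that chromosome exceeded that of other genes (Fisher's exact p = 2.52e-05), but this restates the pattern. It therefore neither favours nor excludes a strain variant carried along with the targeted gene, which stays open. The chromosome of C3ar1, also targeted, held 2 of the 13 genes (Fisher's exact p = 0.140). Sex and neutrophil content were argued against as the whole cause, since the median called gene kept 1.02 of its difference without the arrays with Y-linked signal (leaving 2 DKO arrays) and 0.965 with the neutrophil level as a covariate. Of 60 splits of the arrays, 1, the real one, gave as many calls (13, highest other 1). That share, 0.0167, is the smallest these splits can give, so it argues against chance for this count but does not exclude it. Glo1, Btbd9 and Dnah8 were higher in DKO by 0.86, 0.56 and 0.65. They lay 1 or 2 tested genes from another called gene, on a chromosome with neither C5ar1 nor C3ar1. A variant linked to either targeted gene would not cover them. An effect of the missing receptors on the 13 genes stays open and was not tested.

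The second pattern was the smaller CpG response in DKO. The genes that rose kept 1.25 of their median difference with the neutrophil and macrophage marker levels as covariates and 1.12 after cyclic loess. This argues against neutrophil and macrophage content, and against scaling differences that a second normalization of the deposited values would remove. The content of other cells, DC subsets among them, was not tested. The genes that rose kept 1.08 with Y-linked signal as a covariate, which argues against a sex effect of the same size with and without CpG. Without the arrays with that signal they kept 1.27, but this rests on 1 DKO array without stimulation and 1 after CpG, the weakest responder. A response that depends on sex therefore stays open. Leaving out any 1 DKO CpG array kept at least 0.866 with the same genes, but -0.08 instead of -0.15 remained without DKO CpG 3 when the genes were chosen again, so 1 weakly responding array is argued against only for a fixed set of genes. Chance was not excluded, since 10 of 60 splits gave a median as large (0.15, highest other 0.25). Some splits carry a genotype difference into the difference of effects, so they cannot decide alone. For the genes that rose, camera with the estimated correlation gave p = 0.0111 and fry p = 0.0357. An effect of genotype stays open and untested.

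The third pattern was low neutrophil and macrophage markers in part of the DKO arrays. The 5 WT arrays carry no Y-linked signal and lay on average 1.39 above the DKO arrays without it in macrophage markers, and the neutrophil difference kept 1.38 of its median without the arrays with Y-linked signal (leaving 2 DKO arrays) and 0.918 without the second title series, which argues against sex for both and against the series for neutrophil markers as the whole cause. In macrophage markers the WT array of the series lay 1.44 above the higher of its DKO arrays, but this is 1 array, its 2 DKO arrays are also those without Y-linked signal, and without the series the averaged genotype shift went from -0.62 to 0.049, so the series stays open for them. Within groups the members of each list moved together (median correlation 0.791 for neutrophil and 0.928 for macrophage markers, against 0.101 and 0.0997, exceeded by 1 in 20 of 1000 random lists), so varying amounts of these cells in the bead isolates may be a source. Whether genotype changes these cells in the spleen stays open and untested.

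For CpG averaged over genotypes, 1 of 100 splits, the real one, gave as many calls (3978, highest other 347), which argues against chance. The costimulation list averaged over stimulation shifted as far in 1 of 60 splits, the real one (size 0.29, highest other 0.19). This argues against chance for this list taken alone but not after adjustment over the 26 lists (adjusted exact p = 0.0867). For the genes differing after CpG, 1 of 10 splits gave as many calls (16, highest other 0), and for the costimulation list after CpG 1 of 10 gave a shift as large (size 0.36, highest other 0.20), and the splits are too few for a share under 0.05.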

How the results depend on the processing

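Leaving out the genes of the X and Y chromosomes, leaving out the arrays with Y-linked signal or of the second title series, and the covariates (Y-linked signal, neutrophil or macrophage level) were tests chosen only after the result was seen. Except where a change follows by construction, the cause was not tested.

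Counts of genes changed by CpG in DKO were 2183 at an adjusted p under 0.10, by construction, 402 in a fit on only the groups compared and 408 without the arrays with Y-linked signal. CpG averaged over genotypes gave 1742 at a fold of at least 1.5, by construction. Between genotypes after CpG the count was 38 at the 75th percentile filter, 76 with trend and robust, 125 with array weights, 296 with the title series as a block, 253 at an adjusted p under 0.10, 3 with only the groups compared, 723 without the arrays with Y-linked signal, 738 with it as a covariate, 90 without the second title series, and 9 and 124 with the neutrophil and macrophage covariates. Averaged over stimulation it was 8, 20, 33, 50 and 47 for the first 5 of these settings, 987 and 869 for the sex-linked settings, 59 without the second title series, and 3 and 22 with the neutrophil and macrophage covariates. Without stimulation it was 2 with the title series as a block, 12 with only the groups compared, 250 and 382 for the sex-linked settings, 23 without the second title series and 6 with the macrophage covariate. For the difference of the CpG effects limma called 0 genes with the 75th percentile filter, quantile normalization, a median shift, the title series as a block, the arrays with Y-linked signal left out or the neutrophil covariate, against 756 at an unadjusted p under 0.05 with the settings used throughout, and 2 without the second title series.

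C3ar1 passed at -0.81 in both sex-linked settings. C5ar1 passed at -1.58 with array weights, -1.40 with the title series as a block, -1.54 in both sex-linked settings and -1.79 without the second title series. The 75th percentile filter removed both receptors and gave no value. Camera called 71 list shifts, camera with the estimated correlation 7, all among the 71, and fry 28, of which 25 were among the 71. The similarity of the CpG responses was 0.761 without a filter, 0.871 at the 75th percentile and 0.697 without the arrays with Y-linked signal.

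Leaving out 1 array gave 1277 to 3226 genes for CpG in WT, 423 to 1909 in DKO, 2935 to 4288 averaged, 1 to 2 between genotypes without stimulation, 2 to 267 after CpG, 1 to 71 averaged and 0 to 1 for the difference of effects, a similarity of 0.713 to 0.848, 67 to 79 list shifts, -0.73 to -0.54 for C3ar1 and -1.78 to -1.33 for C5ar1. A group left with 1 array is assumed to vary like the others.

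With the neutrophil level as a covariate, lists reversed without stimulation (cytokines 0.037, NF-kB targets 0.025, cell cycle -0.0029, conventional DC markers -0.033), after CpG (cytokines 0.064, complement 0.14, conventional DC markers -0.086) and averaged (cytokines 0.063, chemokines 0.0046, NF-kB targets 0.016, complement 0.035, conventional DC markers -0.070, macrophage markers 0.16). None of these passed camera there (adjusted p from 0.156 to 0.991), so no shift in the opposite direction was shown. Another 13 list calls kept their sign but no longer passed with this covariate. Plasmacytoid markers reversed after CpG with the Y-linked covariate (-0.053) and averaged in both sex-linked settings (-0.10), and ran from -0.025 to 0.28 with 1 array left out. Macrophage markers reversed for the difference of effects with the title series as a block (-0.018) and ran from -0.27 to 1.14 with 1 array left out, and averaged were 0.049 without the second title series. A list has no value with its own level as a covariate. Of the other values, for named genes 10670 were on the same side of the threshold in the same direction, 237 newly passed and 658 no longer passed, and for lists 1645 were on the same side and 243 no longer passed. Values near the array medians may be near background, which limits what the levels of the receptors show.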

Other observations

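Families of genes that share a symbol stem were tested for the CpG effect averaged over genotypes. Of 205 families with at least 8 tested members, camera called 4, and each had an adjusted p = 0.922 with an estimated correlation. The proteasome regulatory subunits (Psmd) had 5 of 14 risen and 1 fallen, with a median of 0.24 (camera adjusted p = 0.0395), and none of them stood in a fixed list. The interleukin and receptor family (Il) had 18 of 47 risen and 5 fallen, with a median of 0.36 (camera adjusted p = 6.37e-07), and a fixed list held 17 of them. The Ifi and Cxcl families each had 9 of 11 risen, with medians of 1.27 and 0.88 (camera adjusted p = 9.06e-06 and 0.000235), and fixed lists held 4 and 10 of their members.

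Igkv4-59, an immunoglobulin variable segment chosen after its values were seen, changed by 4.85 with CpG in DKO (adjusted p = 0.00510) and by 0.41 in WT. The difference of these effects, 4.45 ± 1.13, did not pass (adjusted p = 0.734). Of the genes called for CpG averaged over genotypes, 229 had more than 1 probe set, and 64 of these had a probe set of the opposite sign.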
